A study of Mus musculus with 9 samples.

How the data were processed

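Gene expression was measured on Affymetrix arrays in 9 samples of mouse bone marrow-derived dendritic cells from C57BL/6 mice, 3 given PBS, 3 given live Bordetella and 3 given heat-killed Bordetella. Per the labels, total RNA was biotin-labelled and hybridised to 1 array per sample. The submitters' processing notes name Affymetrix Expression Console as the tool that summarised the probe sets, and its version and the normalization method are not given in the sources used here. The deposited values lay on a log2 scale, as judged from their range and their like quantiles on all 9 arrays, and were used as deposited by the authors. Scanner files were not used here.

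Of the 35556 probe sets, 21789 mapped to 1 gene symbol, 1621 to several symbols and 12146 to no listed gene. Of the first kind, 21698 were matched to the reference annotation by gene ID. Where a gene had more than 1 probe set (998 genes), the probe set with the highest mean over the 9 arrays stood for it, which left 19939 genes. Probe sets of these 998 genes were called in opposite directions for 1 gene in live against PBS, 2 in heat-killed against PBS and 1 in live against heat-killed bacteria. Probe sets with several symbols or none were tested apart. No filter on dim genes was applied.

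Groups were compared with limma 3.58.1 in R 4.3.3 (linear models with empirical Bayes moderation, two-sided) in 1 fit of all 9 arrays, with a prior of 6.72 degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes within each comparison, and genes were called at adjusted p under 0.05. The comparisons were live bacteria against PBS, heat-killed bacteria against PBS, and live against heat-killed bacteria. The overlap of the first 2 was set beside independent lists and beside 20 simulations of unchanged groups against the same PBS arrays. The 33 gene lists held 677 members (658 distinct genes, 591 measured) and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. Camera with an estimated correlation and camera on ranks were alternatives. So was fry, which tests a list against no change where camera tests it against the other genes, so a pass or a miss with fry answers another question. The groups, comparisons, tests, gene lists, the rule for named genes and most alternatives were set before the data were examined. By that rule, named genes were the 10 largest rises and 10 largest falls per comparison among called genes with known symbols whose groups did not overlap, the 4 members of each list with the largest changes, and 14 key genes.

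The origin of the replicates is not stated, so they may be technical, and p-values measure the spread between these samples only. The number of arrays, 3 per group, limits the precision. Replicate numbers recur across groups without a stated pairing, so arrays were taken as independent. The fit was tested on simulated data for live bacteria against PBS. Of 50 genes changed 1.5-fold 49 were called, as were 50 of 50 at 2-fold, 3-fold and 4-fold, and 9 of 208 calls were false (4.33%). Of 75 lists with a simulated log2 shift of 0.3, 75 were called, and of 420 without a shift 4 were called. The simulated genes varied independently of each other. These list counts therefore do not show how often lists of correlated genes would be called falsely. Alternatives were quantile normalization, median centring, filters at the 25th and 50th percentiles of mean signal, the mean of a gene's probe sets, fits of 2 groups alone, moderation with trend and robust set, array weights, each array left out in turn, a replicate block, a 2-fold minimum, adjusted p under 0.01 and adjustment over the 3 comparisons together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.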

Results

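Dendritic cells grown from C57BL/6 mouse bone marrow with GM-CSF, a growth factor for myeloid cells, were profiled after exposure to PBS, to live Bordetella or to heat-killed Bordetella. Bordetella is a genus of Gram-negative bacteria that infect the airways. Cultures of this kind hold dendritic cells beside macrophages and granulocytes. Each group held 3 arrays, 9 in all, and each array measured 35556 probe sets. The species of Bordetella, the dose and the time of exposure are not stated in the labels. Array medians lay between 4.32 and 4.39 on the log2 scale. Replicate arrays correlated across probe sets with Pearson's r of 0.991 to 0.996, whereas live and PBS arrays correlated with r of 0.968 to 0.972 and live and heat-killed arrays with r of 0.990 to 0.992. Genes are not independent replicates, so these correlations describe the arrays only.

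The comparison of live bacteria with PBS asks which transcripts change when the cells meet living Bordetella. Hamp, which encodes the iron hormone hepcidin, had the largest measured rise, from a log2 signal of 3.69 ± 0.29 (SD, n = 3) to 10.54 ± 0.061, a log2 change of 6.85 (SE 0.121, limma adjusted p = 5.86e-13). Il1b, the gene of interleukin 1 beta, rose from 4.87 ± 0.36 to 9.89 ± 0.077 (log2 change 5.02, SE 0.135, adjusted p = 9.37e-12). Mrc1, the macrophage mannose receptor, fell from 9.19 ± 0.16 to 3.44 ± 0.21 (log2 change -5.75, SE 0.142, adjusted p = 4.38e-12). Slc40a1, the iron exporter ferroportin on which hepcidin acts, fell from 7.60 ± 0.26 to 3.30 ± 0.039 (log2 change -4.30, SE 0.105, adjusted p = 4.21e-12). Hamp with PBS, and Mrc1 and Slc40a1 with live bacteria, lay below the median of all values, 4.37, where signal may be background. Their log2 changes, and those of other genes that lay below it in 1 group, are lower bounds if that is so.

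Other large rises with live bacteria were those of Cxcl2, a neutrophil-attracting chemokine (5.34), the type 2 cytokines Il9 (4.95) and Il13 (4.87), the mast cell protease Mcpt2 (4.94), the interferon-inducible Ifi205 (4.62), the inducible cyclooxygenase Ptgs2 (4.56), the trefoil peptide Tff1 (4.52) and the early activation antigen Cd69 (4.42). Other large falls were those of Mamdc2 (-5.61), Bex1 (-5.50), Ceacam10 (-4.65), the lipid carrier Apoe (-4.58), the monoacylglycerol lipase Mgll (-4.41), the growth factor Igf1 (-4.26), the selenium carrier Selenop (-4.25) and the ubiquitin ligase Rnf128 (-4.25). These values are log2 changes, each at a limma adjusted p of 2.01e-09 or below. The rule for naming these genes required that the 3 live arrays all lie on the same side of the 3 PBS arrays. Across the 19939 genes tested, 6055 changed with live bacteria at adjusted p under 0.05, of which 3133 rose and 2922 fell. At least 2-fold changes were seen in 475 of the rising and 742 of the falling genes. The live and PBS arrays did not overlap in 40% of genes, where chance gives 10%. The median SE of a log2 change was 0.0845.

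Cytokine and chemokine transcripts rose with live bacteria. Of the 22 inflammatory cytokines measured, 15 rose and 3 fell (16 and 3 adjusted over the list alone), with a median log2 change of 0.65 (camera adjusted p = 1.91e-07). Il6 rose by 4.20 and Tnfsf15, a ligand of the tumour necrosis factor family, by 3.58, whereas the interleukin 1 family member Il1f9 fell (-3.28). Tnf changed less, at 0.79 (SE 0.0759, adjusted p = 1.99e-06), and Il12b, the shared subunit of interleukins 12 and 23, rose by 0.48 (adjusted p = 4.38e-04). Il23a (0.26, adjusted p = 0.0305) and the anti-inflammatory Il10 (0.47, adjusted p = 0.00344) also rose, from signals below the median of all values, 4.37, in every group. Il23a lost its call without PBS replicate 1 (0.0858), PBS replicate 3 (0.0947), live replicate 1 (0.127) or live replicate 2 (0.0811), or with quantile normalization (0.055) or median centring (0.0534), against a range of 0.0173 to 0.127 over its alternatives. Among the 22 chemokines, 16 rose and 1 fell (17 and 1 adjusted over the list alone, median 1.02, camera adjusted p = 4.65e-10), led by Cxcl2, Ccl17 (4.04), Cxcl3 (2.98) and Cxcl1 (2.18). Cxcl10, a chemokine induced by interferon, rose by 1.69 (adjusted p = 3.54e-09).

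Genes that interferons induce and genes of dendritic cell maturation rose together. Of 33 interferon-stimulated genes, 28 rose and 0 fell (28 and 0 adjusted over the list alone, median 1.35, camera adjusted p = 4.35e-21), with examples in the guanylate-binding protein Gbp5 (3.47), Ifit1 (2.91) and Oasl2 (2.76). The type I interferon genes themselves were mostly dim: 3 of 13 lay above the median of all values with PBS, 2 rose and 0 fell (2 and 0 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.502). Ifnk rose by 0.76 (adjusted p = 7.83e-05) and Ifnb1 by 0.28 (adjusted p = 0.0174), to a mean of 3.24 ± 0.055. Ifnb1 lost its call without PBS replicate 1 (0.0807) or live replicate 2 (0.0671), or without both PBS replicate 2 and live replicate 3 (0.0799), against a range of 0.00844 to 0.0807 over its alternatives. Pairs of arrays left out together were chosen after the data were seen, here and below. Of 21 dendritic cell maturation genes, 17 rose and 1 fell (18 and 2 adjusted over the list alone, median 1.04, camera adjusted p = 4.99e-12). The costimulatory receptors and ligands Cd86 (2.42), Tnfsf9 (2.37), Cd40 (2.27) and Cd80 (1.99) led this list, and Ccr7, the receptor that guides dendritic cells to lymph nodes, rose by 0.52 (adjusted p = 1.44e-04) from an already high 10.84 ± 0.073. Among 24 NF-kappaB pathway and feedback genes, 21 rose and 0 fell (21 and 0 adjusted over the list alone, camera adjusted p = 4.99e-12), including Nfkbiz (2.06) and the inhibitors Tnfaip3 (1.50) and Nfkbia (1.47). Of 15 MHC class I presentation genes, 10 rose and 1 fell (10 and 2 adjusted over the list alone, camera adjusted p = 2.19e-04, adjusted p = 0.152 with an estimated correlation), led by the peptide transporter Tap1 (1.63) and the immunoproteasome subunit Psmb9 (1.16). Among 23 cAMP-responsive genes, 14 rose and 4 fell (15 and 5 adjusted over the list alone, camera adjusted p = 0.00172, adjusted p = 0.182 with an estimated correlation). The members went both ways: the nuclear receptor Nr4a2 rose by 1.51 and the phosphatase Dusp1 by 1.41, while the transcription factors Atf3 (-1.48) and Egr2 (-1.33) fell.

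Macrophage and phagocytic genes fell with live bacteria. Of 23 phagocytic and lectin receptors, 2 rose and 17 fell (2 and 17 adjusted over the list alone, median -2.22, camera adjusted p = 3.07e-13), with Fcgr4, an IgG receptor (-4.01), Mertk, a receptor for dying cells (-3.68), and the scavenger receptor Cd36 (-3.48) among the largest falls. Of 14 macrophage markers, 2 rose and 9 fell (2 and 9 adjusted over the list alone, median -1.69, camera adjusted p = 3.47e-06), 3 of them shared with the phagocytic list. The complement subunit C1qb fell (-3.82), as did Csf1r, the receptor of the macrophage growth factor (-3.43). Of 21 lysosome and autophagy genes, 1 rose and 16 fell (1 and 16 adjusted over the list alone, median -0.99, camera adjusted p = 1.49e-10), led by the protease Ctsk (-3.10) and the proton pump subunit Atp6v0d2 (-2.99). Of 17 oxidative stress response genes, 1 rose and 12 fell (1 and 13 adjusted over the list alone, median -1.23, camera adjusted p = 2.13e-09), including the quinone reductase Nqo1 (-3.44), the glutathione synthesis subunit Gclm (-2.87) and the haem oxygenase Hmox1 (-1.94). Of 22 toll-like receptors and adaptors, 5 rose and 13 fell (5 and 14 adjusted over the list alone, median -0.36, camera adjusted p = 0.00103, adjusted p = 0.227 with an estimated correlation): the endosomal receptors Tlr8 (-3.89), Tlr13 (-3.76) and Tlr7 (-3.52) fell, and the lipopolysaccharide co-receptor Cd14 rose (1.75).

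Sterol genes moved in opposite ways by function. Of 20 sterol biosynthesis genes, 16 rose and 2 fell (17 and 2 adjusted over the list alone, median 0.83, camera adjusted p = 1.03e-07), among them Stard4, a sterol carrier (1.37), and the farnesyl diphosphate synthase Fdps (1.33). Dhcr7, the enzyme of the last step to cholesterol, fell (-1.49). Of 11 sterol efflux and LXR target genes, 0 rose and 9 fell (0 and 9 adjusted over the list alone, median -1.14, camera adjusted p = 1.03e-07), including Nr1h3, which encodes LXR alpha (-1.64), and the cholesterol 25-hydroxylase Ch25h (-2.02). Of 17 glycolysis genes, 1 rose and 9 fell (2 and 10 adjusted over the list alone, median -0.36, camera adjusted p = 0.00327, adjusted p = 0.204 with an estimated correlation), with falls of the glucose transporter Slc2a1 (-1.11) and of Pgam1 (-1.03). The glycolysis call ended when genes under the 50th percentile of mean signal were left out (adjusted p = 0.0648, against a range of 8.33e-05 to 0.204 over its alternatives). Of 28 oxidative phosphorylation genes, 0 rose and 15 fell (1 and 16 adjusted over the list alone, median -0.21, camera adjusted p = 1.75e-05, adjusted p = 0.133 with an estimated correlation). The succinate dehydrogenase subunit Sdhb was at -0.77.

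Markers of other cell types were also followed. Of 16 mast cell, basophil and eosinophil markers, 9 rose and 0 fell (9 and 1 adjusted over the list alone, median 0.57, camera adjusted p = 0.00112, adjusted p = 0.227 with an estimated correlation). The mast cell protease Cpa3 was at 2.95 (adjusted p = 5.93e-07) and the histamine-forming enzyme Hdc at 2.00. The other 16 lists did not pass. Of 18 neutrophil and myeloid precursor markers, 1 rose and 4 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.0797), with the chitinase-like Chil3 at -2.80. Fry, unlike camera, tests a list against no change, not against the other genes. The neutrophil list passed, downward, without PBS replicate 2 (0.0362) or live replicate 1 (0.0419), or with fry (0.0129), against a range of 0.0129 to 0.515 over its alternatives. Of 16 conventional dendritic cell markers, 9 rose and 4 fell (9 and 4 adjusted over the list alone, camera adjusted p = 0.0636), and the list passed, upward, without PBS replicate 1 (0.039), or with median centring (0.0455) or fry (0.00166), against a range of 0.00166 to 0.198 over its alternatives. The kynurenine enzyme Kmo was at 2.36 and the lectin Clec9a at -2.84. Of 8 plasmacytoid dendritic cell markers, 1 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.43), and of 13 erythroid and stromal markers, 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.341). Of 16 lymphocyte markers, 0 passed limma, over all genes or adjusted over the list alone (camera adjusted p = 0.354). Only 5 of the 16 lay above the array median with PBS and 5 with live bacteria, so background may hide changes in most of them. 4 of the 16 had an unadjusted p under 0.05. Of 23 antimicrobial effectors, 11 rose and 6 fell (11 and 6 adjusted over the list alone, camera adjusted p = 0.239): the inducible nitric oxide synthase Nos2 (3.38), the itaconate enzyme Acod1 (1.52) and the siderophore binder Lcn2 (2.84) rose, and the NADPH oxidase subunit Cybb fell (-3.14). Of 16 prostanoid and leukotriene genes, 5 rose and 6 fell (5 and 7 adjusted over the list alone, camera adjusted p = 0.408), Ptgs2 rising while the thromboxane synthase Tbxas1 fell (-3.16). Of 12 arginine and tryptophan metabolism genes, 6 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.111). The tryptophan-degrading Ido1 was at 3.20. Of 15 anti-inflammatory mediators, 8 rose and 5 fell (9 and 5 adjusted over the list alone, camera adjusted p = 0.0602), and the list passed, upward, without PBS replicate 1 (0.039), PBS replicate 2 (0.0471) or PBS replicate 3 (0.0451), or with median centring (0.0371) or fry (7.65e-05), against a range of 7.65e-05 to 0.374 over its alternatives. The cytokine signalling inhibitor Cish was at 2.86 and the inhibitory receptor Cd200r1 at -3.32.

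The remaining lists held changes in both directions. Of 15 MHC class II presentation genes, 7 rose and 6 fell (7 and 7 adjusted over the list alone, camera adjusted p = 0.859), the class II transactivator Ciita rising (1.46) and the cathepsins Ctsb (-1.93) and Ctsd (-1.44) falling, with a list median of 0.14 and a mean of -0.0672. Of 17 inflammasome and pyroptosis genes, 3 rose and 6 fell (3 and 7 adjusted over the list alone, camera adjusted p = 0.699). The inflammatory caspase Casp4 was at 1.29. Of 20 unfolded protein and integrated stress response genes, 5 rose and 6 fell (7 and 6 adjusted over the list alone, camera adjusted p = 0.975). The stress sensor Ern1 was at 1.62. Of 12 heat shock proteins, 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.439). The co-chaperone Bag3 was at -1.25. Of 18 apoptosis and survival genes, 6 rose and 4 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.619). The necroptosis kinase Ripk3 was at -1.44. Of 29 cell cycle genes, 6 rose and 4 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.43). The thymidylate synthase Tyms was at 1.90. The median, mean and test of the MHC class II, inflammasome and apoptosis lists differed in sign. With fry, which asks another question than camera, 5 more lists passed, in the direction given: MHC class II presentation (down, 0.0075, range 0.0075 to 0.987), antimicrobial effectors (up, 0.0146, range 0.0146 to 0.53), arginine and tryptophan metabolism (up, 1.53e-04, range 1.53e-04 to 0.336), prostanoid and leukotriene genes (down, 1.23e-04, range 1.23e-04 to 0.658) and erythroid and stromal markers (up, 0.0207, range 0.0207 to 0.601), with each range taken over the alternatives of that list. In all, 17 of the 33 lists passed, 9 higher and 8 lower, and 11 of them also passed with an estimated correlation.

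**Figure D1:**
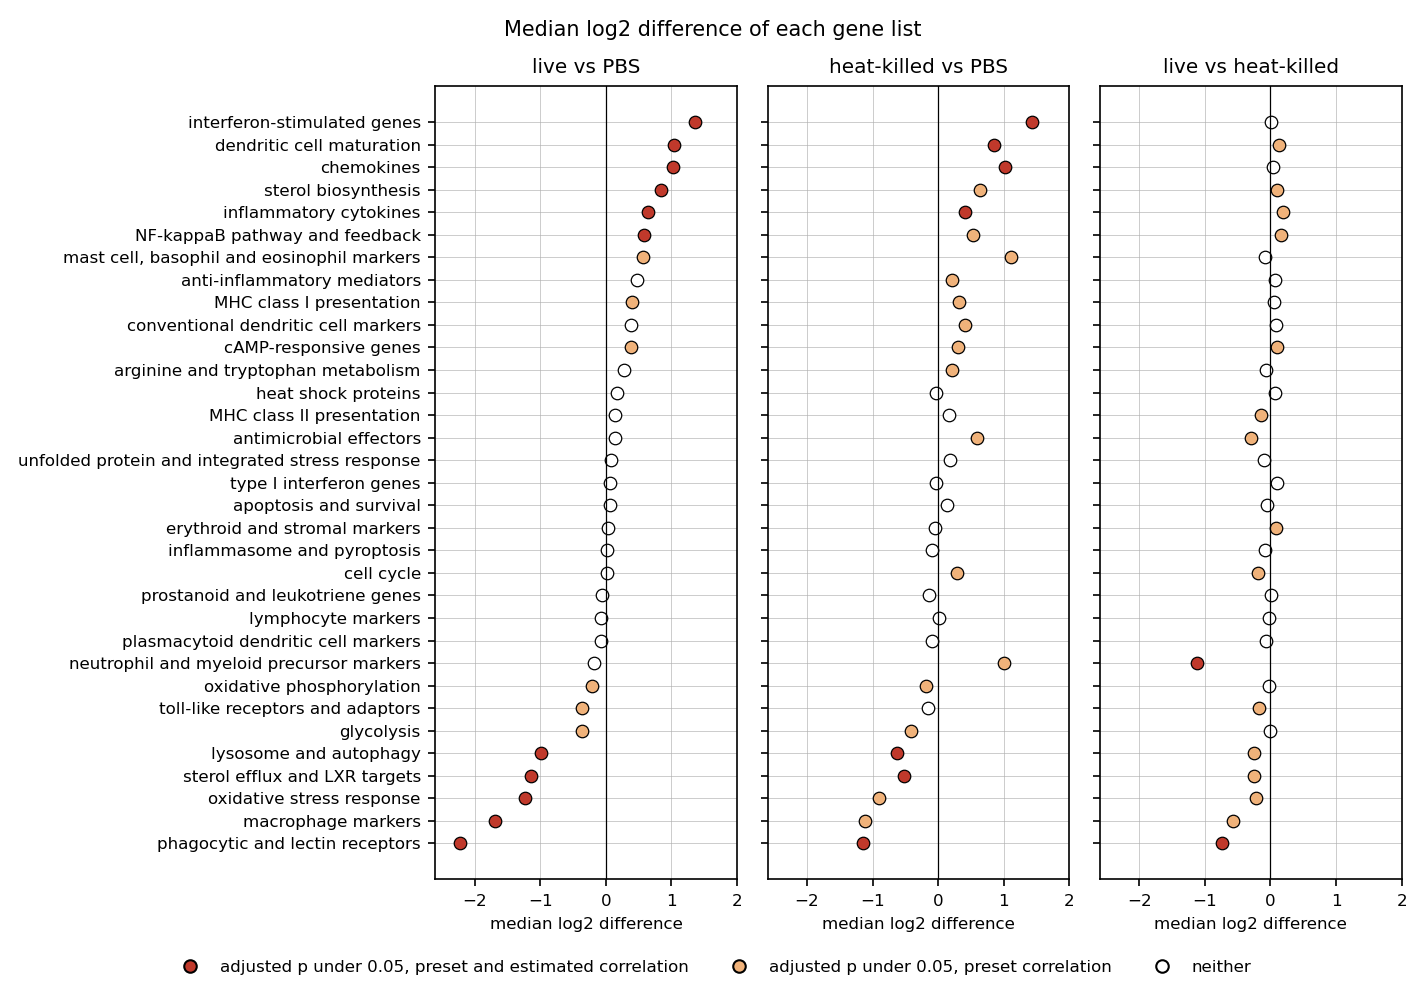
Median log2 difference of the measured members of each of the 33 gene lists (horizontal axis, log2 units) in the 3 comparisons (panels), with lists ordered by their median with live bacteria against PBS; red points passed camera at adjusted p under 0.05 with the preset and with an estimated correlation, orange points with the preset correlation alone, and white points passed neither. Interferon-stimulated genes stood highest against PBS, at 1.35 with live and 1.43 with heat-killed bacteria, phagocytic and lectin receptors lowest, at -2.22 and -1.15, and neutrophil and myeloid precursor markers were lowest in the direct comparison, at -1.12.

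Heat-killed bacteria were compared with PBS to see which transcripts change with bacteria that cannot multiply. Several of the leading genes were also among the 10 largest rises or falls with live bacteria, and others, such as Serpinb2, Ccnd2 and Cd5l, were not. Cxcl2 rose from 4.81 ± 0.56 (SD, n = 3) to 9.73 ± 0.11 (log2 change 4.92, SE 0.195, limma adjusted p = 6.67e-10) and Hamp to 8.33 ± 0.12 (log2 change 4.64, SE 0.121, adjusted p = 3.53e-11). Serpinb2, an inhibitor of plasminogen activators, rose from 6.05 ± 0.18 to 10.58 ± 0.14 (log2 change 4.54, SE 0.0967, adjusted p = 6.16e-12). Bex1 fell from 8.13 ± 0.37 to 2.93 ± 0.14 (log2 change -5.21, SE 0.145, adjusted p = 4.98e-11). Il1b (4.51), Tff1 (4.22), Cd69 (4.15), Ccl17 (3.94), the cyclin Ccnd2 (3.93), Kctd14 (3.71) and Lcn2 (3.66) completed the 10 largest rises. Mamdc2 (-4.85), Mrc1 (-4.29), Apoe (-4.20), Slc40a1 (-3.84), the macrophage-secreted Cd5l (-3.82), Selenop (-3.65), the monoamine oxidase Maoa (-3.63), Tlr8 (-3.27) and Pgap1 (-3.19) completed the 10 largest falls. Il6 (3.60), Tnf (1.20), Ptgs2 (3.46), Nos2 (2.13), Acod1 (1.71), Cxcl10 (2.15), Cd86 (2.29), Cd40 (1.46) and Ccr7 (0.38) rose as well. Il12b (0.05, adjusted p = 0.711), Il10 (0.06, 0.739), Il23a (0.02, 0.905) and Ifnb1 (0.18, 0.119) did not pass. Ifnb1 did pass with array weights (0.0494), against a range of 0.0494 to 0.367 over its alternatives. With heat-killed bacteria 5835 of the 19939 genes changed at adjusted p under 0.05, 3161 higher and 2674 lower, of which 403 and 520 changed at least 2-fold. The heat-killed and PBS arrays did not overlap in 39.2% of genes, against 10% by chance.

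Of the 33 lists, 22 passed for heat-killed bacteria against PBS, 15 higher and 7 lower, and 7 of these also passed with an estimated correlation. These 7 are described first. Of the interferon-stimulated genes, 32 rose and 0 fell (32 and 0 adjusted over the list alone, median 1.43, camera adjusted p = 8.07e-28). Of the chemokines, 16 rose and 0 fell (16 and 0 adjusted over the list alone, camera adjusted p = 5.37e-14). Of the dendritic cell maturation genes, 17 rose and 0 fell (19 and 0 adjusted over the list alone, camera adjusted p = 2.06e-13). Of the inflammatory cytokines, 13 rose and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 6.21e-07). Of the phagocytic and lectin receptors, 2 rose and 16 fell (2 and 16 adjusted over the list alone, median -1.15, camera adjusted p = 9.88e-10). Of the lysosome and autophagy genes, 1 rose and 14 fell (1 and 17 adjusted over the list alone, camera adjusted p = 9.88e-10). Of the sterol efflux and LXR targets, 1 rose and 7 fell (1 and 8 adjusted over the list alone, camera adjusted p = 3.72e-05). Ifit1 rose by 3.00, Ifit3, another interferon-induced gene, by 2.96, and the chemokines Cxcl3 by 3.12 and Ccl7 by 2.63. Fcgr4 (-2.70), Cd36 (-2.14) and Ctsk (-2.82) fell. Of the NF-kappaB list, 20 rose and 0 fell (21 and 0 adjusted over the list alone, camera adjusted p = 1.48e-11, adjusted p = 0.0524 with an estimated correlation). In sterol biosynthesis, 15 rose and 2 fell (16 and 2 adjusted over the list alone, camera adjusted p = 3.43e-07, adjusted p = 0.0595 with an estimated correlation). Among oxidative stress genes, 1 rose and 12 fell (1 and 12 adjusted over the list alone, camera adjusted p = 2.42e-08, adjusted p = 0.0524 with an estimated correlation). Nqo1 fell (-3.01). Of the macrophage markers, 3 rose and 8 fell (3 and 8 adjusted over the list alone, camera adjusted p = 6.31e-05, adjusted p = 0.0715 with an estimated correlation). For MHC class I genes, 10 rose and 1 fell (10 and 2 adjusted over the list alone, camera adjusted p = 4.65e-04, adjusted p = 0.128 with an estimated correlation). Of the glycolysis genes, 0 rose and 11 fell (1 and 11 adjusted over the list alone, camera adjusted p = 6.59e-05, adjusted p = 0.105 with an estimated correlation). For oxidative phosphorylation, 0 rose and 11 fell (0 and 14 adjusted over the list alone, camera adjusted p = 4.35e-05, adjusted p = 0.11 with an estimated correlation).

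Granulocyte markers were higher with heat-killed bacteria than with PBS. Of the 18 neutrophil and myeloid precursor markers, 13 rose and 1 fell (13 and 1 adjusted over the list alone, median 1.01, camera adjusted p = 2.43e-05, adjusted p = 0.11 with an estimated correlation). The granule proteins Camp, a cathelicidin, and Ltf, lactoferrin, rose by 2.88 (SE 0.451, adjusted p = 2.43e-04) and 2.68 (SE 0.406, adjusted p = 1.85e-04), Ngp by 2.55 and the neutrophil surface marker Ly6g by 2.55 (adjusted p = 7.47e-05). Replicates differed widely for these genes: Ngp measured 7.26, 5.56 and 7.44 on the 3 PBS arrays and 9.44, 8.66 and 9.83 on the heat-killed arrays. Of the 16 mast cell, basophil and eosinophil markers, 11 rose and 0 fell (11 and 0 adjusted over the list alone, median 1.11, camera adjusted p = 4.68e-05, adjusted p = 0.125 with an estimated correlation). Cpa3 was at 3.30 and Prg2, the eosinophil major basic protein, at 2.91 (SE 0.599, adjusted p = 0.00205). The Prg2 rise became 1.88 without PBS replicate 2. Antimicrobial effectors, a list that holds Camp, rose beside the granulocyte markers: 14 rose and 6 fell (15 and 7 adjusted over the list alone, camera adjusted p = 0.0015, adjusted p = 0.11 with an estimated correlation). The acute phase protein Saa3 was at 2.95. Among cell cycle genes, 14 rose and 1 fell (19 and 1 adjusted over the list alone, camera adjusted p = 6.15e-05, adjusted p = 0.105 with an estimated correlation). Tyms was at 1.67 and the replication helicase subunit Mcm3 at 0.90. Of the conventional dendritic cell markers, 9 rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.0246, adjusted p = 0.11 with an estimated correlation), a call lost with the 50th percentile filter (0.128), against a range of 7.57e-04 to 0.128 over its alternatives. Among the cAMP-responsive genes, 13 rose and 4 fell (14 and 4 adjusted over the list alone, camera adjusted p = 0.00689, adjusted p = 0.187 with an estimated correlation), a call lost with the 50th percentile filter (0.086), against a range of 0.00106 to 0.187 over its alternatives. Among anti-inflammatory mediators, 7 rose and 3 fell (7 and 3 adjusted over the list alone), and the list passed (camera adjusted p = 0.0374, adjusted p = 0.307 with an estimated correlation). It did not pass with the 25th percentile filter (0.0781), the 50th percentile filter (0.186) or camera on ranks (0.263), against a range of 8.09e-05 to 0.307 over its alternatives. The median of 0.21 became 0.369 without PBS replicate 3. In the arginine and tryptophan list, 6 rose and 3 fell (7 and 3 adjusted over the list alone), and it passed (camera adjusted p = 0.0374, adjusted p = 0.187 with an estimated correlation). It did not pass without PBS replicate 2 (0.0548) or heat-killed replicate 2 (0.0543), or with the 25th percentile filter (0.0781), the 50th percentile filter (0.204) or camera on ranks (0.0705), or without both PBS replicate 2 and heat-killed replicate 2 (0.0804), against a range of 1.06e-04 to 0.204 over its alternatives. Of the toll-like receptors and adaptors, 7 rose and 10 fell (7 and 10 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0753). It did pass, downward, without PBS replicate 3 (0.029) or heat-killed replicate 2 (0.0428), or with fry (8.66e-04), against a range of 8.66e-04 to 0.499 over its alternatives. Tlr13 was at -2.17. Prostanoid and leukotriene genes did not pass (camera adjusted p = 0.34), except, downward, with fry (adjusted p = 8.39e-04, the lowest of a range up to 0.499 over its alternatives). Median, mean and test differed in sign for 4 lists that did not pass, namely type I interferon genes, inflammasome and pyroptosis, lymphocyte markers, and erythroid and stromal markers.

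The responses to the live and heat-killed preparations were set side by side. In both comparisons 4853 genes were called in the same direction, 2525 higher and 2328 lower, among them Il1b, Cxcl2, Hamp, Mrc1, Apoe and Bex1. Independent lists of these sizes would share 889 genes in the same direction. Unchanged groups simulated against the same PBS arrays, 20 times, shared 0, which is no yardstick for the count, since groups without effects give almost no calls. Across genes the log2 changes correlated with r = 0.924, against a mean of 0.5 in the simulations, and their covariance was 0.239, against 0.00426 simulated. The simulated covariance of 0.00426 is what the shared arrays give at the spread between replicates. The 3 PBS arrays are too few to split between the comparisons, so a larger shared part cannot be excluded. Of the 4853 genes, 70.2% changed more with live bacteria, and 706 also differed in the direct test, 645 of them changing more with live and 61 more with heat-killed bacteria. Called in opposite directions were 17 genes, 16 lower with live and higher with heat-killed bacteria and 1 the reverse. Among the 16 were Chil3 (-2.80 and 1.00), Ch25h (-2.02 and 0.49), the calprotectin subunit S100a8 (-1.38 and 1.04) and Tlr2 (-0.54 and 0.38). In 3 of these the rise with heat-killed bacteria lost its call when 1 array was left out. Ch25h lost it without PBS replicate 1 (0.107), PBS replicate 3 (0.101), heat-killed replicate 2 (0.078) or heat-killed replicate 3 (0.082), against a range of 9.54e-05 to 0.107 over its alternatives. S100a8 lost it without PBS replicate 1 (0.0695), PBS replicate 2 (0.0612), heat-killed replicate 1 (0.088) or heat-killed replicate 3 (0.0854), or with trend and robust moderation (0.141), against a range of 6.85e-04 to 0.141 over its alternatives, and its fall with live bacteria became -0.91 without live replicate 3. That fall lost its call with trend and robust moderation (0.0593), against a range of 0.00121 to 0.0593 over its alternatives. Tlr2 lost it without PBS replicate 3 (0.0586) or heat-killed replicate 3 (0.0624), against a range of 0.0059 to 0.0624 over its alternatives. The reverse was Itgb8, an integrin that activates latent TGF-beta (0.85 and -0.60).

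**Figure D2:**
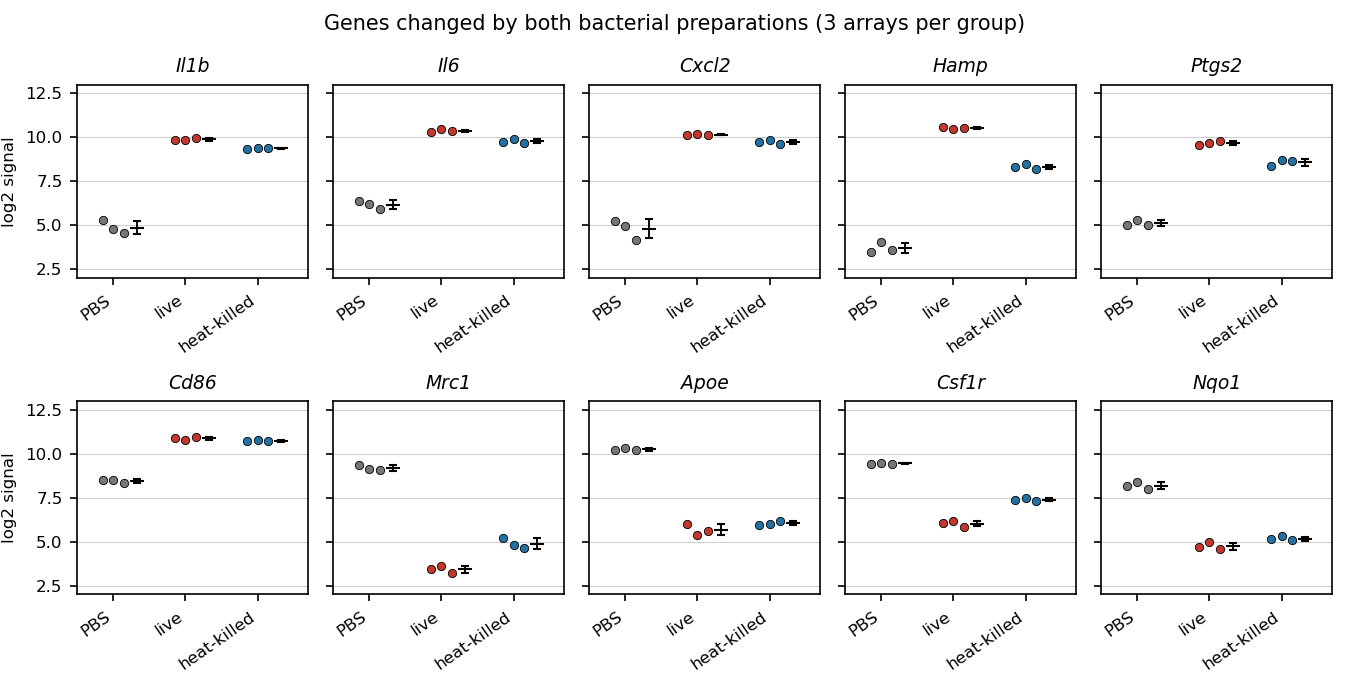
Log2 signal (vertical axis) of 10 genes on each array with PBS (grey), live (red) and heat-killed bacteria (blue); each point is 1 of 3 arrays per group, and the bar with whiskers beside the points is the group mean ± SD. Il1b, Il6, Cxcl2, Hamp, Ptgs2 and Cd86 lay higher and Mrc1, Apoe, Csf1r and Nqo1 lower on all 6 arrays with bacteria than on the 3 PBS arrays; Hamp, for example, had means of 3.69 ± 0.29, 10.54 ± 0.061 and 8.33 ± 0.12.

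The direct comparison of live with heat-killed bacteria asks how the cells differ between the preparations. The dose and time of exposure are not stated, so a difference cannot be put down to bacterial life alone. Genes differed in both directions between the preparations. Il9 measured 8.80 ± 0.20 (SD, n = 3) with live and 4.49 ± 0.64 with heat-killed bacteria, a log2 difference of 4.31 (SE 0.239, limma adjusted p = 2.11e-07). Pth, which encodes parathyroid hormone, measured 6.22 ± 0.19 and 3.06 ± 0.19 (difference 3.16, SE 0.11, adjusted p = 6.08e-09), and with PBS 2.92 ± 0.089. Chil3 measured 5.71 ± 0.16 and 9.51 ± 0.19 (difference -3.80, SE 0.111, adjusted p = 1.40e-09). The other large rises were those of Mcpt2 (3.62), Mcpt1, another mast cell protease (2.73), Hamp (2.21), Il13 (1.71), Itm2a (1.67), the opioid precursor Penk (1.61), the neuropeptide precursor Nts (1.53, adjusted p = 0.00222) and Itgb8 (1.45). The other large falls were those of Ngp (-3.57, SE 0.479), Ltf (-3.37), the kallikrein Klk1b11 (-3.32), Camp (-2.92), Ifitm6 (-2.88), the protease inhibitor Stfa2 (-2.83), Prg2 (-2.77, adjusted p = 0.0149), Ch25h (-2.52) and S100a8 (-2.43). Il9 and Mcpt1 changed with live bacteria against PBS, and did not pass with heat-killed bacteria (0.64, adjusted p = 0.0613, and 0.03, adjusted p = 0.965). Il13 and Mcpt2, in contrast, lay above PBS with heat-killed bacteria too. For both, the rise over PBS with live bacteria exceeded the difference between the preparations (4.87 against 1.71 for Il13). The Il9 change with heat-killed bacteria did pass without heat-killed replicate 1 (0.0233) or heat-killed replicate 2 (0.0366), or with the replicate block (0.0058), the 25th percentile filter (0.0496) or the 50th percentile filter (0.0431), against a range of 0.0058 to 0.193 over its alternatives. The fall of Prg2 lost its call without live replicate 2 (0.0596), live replicate 3 (0.0671), heat-killed replicate 1 (0.0564) or heat-killed replicate 3 (0.0503), or with trend and robust moderation (0.165), or without both live replicate 3 and heat-killed replicate 2 (0.151), against a range of 5.80e-07 to 0.165 over its alternatives. That of Camp lost it with trend and robust moderation (0.0565), against a range of 1.38e-06 to 0.0565 over its alternatives.

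Of the 14 key genes, 9 differed between the preparations. Il6 (0.60), Il1b (0.52, adjusted p = 0.0435), Il12b (0.43), Il10 (0.41, adjusted p = 0.0414), Nos2 (1.25), Ptgs2 (1.10) and Cd40 (0.81) were higher and Tnf (-0.41) and Cxcl10 (-0.47) lower with live bacteria. Il23a (0.24, SE 0.0824), Ifnb1 (0.10, SE 0.08), Acod1 (-0.19, SE 0.094), Cd86 (0.13, SE 0.0743) and Ccr7 (0.14, SE 0.0781) did not pass. The Il1b difference lost its call without live replicate 1 (0.0958), live replicate 2 (0.0937), live replicate 3 (0.17), heat-killed replicate 1 (0.126), heat-killed replicate 2 (0.103) or heat-killed replicate 3 (0.121), or without both live replicate 3 and heat-killed replicate 2 (0.288), against a range of 7.99e-04 to 0.288 over its alternatives. That of Il10 lost it without PBS replicate 1 (0.0578), live replicate 1 (0.105), live replicate 2 (0.119), live replicate 3 (0.123), heat-killed replicate 1 (0.146), heat-killed replicate 2 (0.0623) or heat-killed replicate 3 (0.126), or with quantile normalization (0.0618) or median centring (0.0574), or without both live replicate 3 and heat-killed replicate 2 (0.161), against a range of 0.0041 to 0.161 over its alternatives. Without both live replicate 3 and heat-killed replicate 2, 3 more lost theirs: Tnf (0.0622, range 0.00143 to 0.0622 over its alternatives), Il12b (0.0846, range 2.29e-04 to 0.0846) and Cxcl10 (0.077, range 0.00158 to 0.077). In total 1056 of 19939 genes differed at adjusted p under 0.05, 314 higher and 742 lower with live bacteria, and 25 and 105 of these by at least 2-fold. The groups did not overlap in 22.4% of genes, where chance gives 10%. The count of higher genes fell to 202 without live replicate 1, 192 without live replicate 3 and 194 without heat-killed replicate 3.

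Of the 33 lists, 16 passed between live and heat-killed bacteria, 6 higher and 10 lower, and 2, described first, also passed with an estimated correlation. Of the neutrophil and myeloid precursor markers, 0 rose and 15 fell (0 and 15 adjusted over the list alone, median -1.12, camera adjusted p = 5.86e-22). Of the phagocytic and lectin receptors, 0 rose and 17 fell (1 and 17 adjusted over the list alone, median -0.74, camera adjusted p = 6.33e-25). The scavenger receptor Msr1 (-1.89), the lectin Clec4a2 (-1.82) and the integrin Itgam (-1.38) fell. Of the macrophage markers, 2 rose and 8 fell (2 and 9 adjusted over the list alone, camera adjusted p = 4.79e-08, adjusted p = 0.0607 with an estimated correlation). C1qb was at -1.73 and Csf1r at -1.37. Antimicrobial effectors passed downward: 2 rose and 10 fell (3 and 12 adjusted over the list alone, camera adjusted p = 1.78e-07, adjusted p = 0.0607 with an estimated correlation). Cybb was at -1.55 and the lysozyme Lyz2 at -1.47. Of the toll-like receptors and adaptors, 1 rose and 7 fell (1 and 8 adjusted over the list alone, camera adjusted p = 1.37e-06, adjusted p = 0.134 with an estimated correlation). Tlr13 was at -1.59 and Tlr2 at -0.92. Oxidative stress genes were lower too, and 0 rose and 7 fell (0 and 11 adjusted over the list alone, camera adjusted p = 4.79e-08, adjusted p = 0.0607 with an estimated correlation). Of the lysosome genes, 0 rose and 6 fell (0 and 11 adjusted over the list alone, camera adjusted p = 1.16e-07, adjusted p = 0.0607 with an estimated correlation). Among sterol efflux and LXR targets, 0 rose and 3 fell (1 and 6 adjusted over the list alone, camera adjusted p = 2.61e-04, adjusted p = 0.0607 with an estimated correlation). The lysosome median of -0.25 became -0.145 without heat-killed replicate 2. Of the cell cycle genes, 0 rose and 7 fell (0 and 12 adjusted over the list alone, camera adjusted p = 2.48e-07, adjusted p = 0.0607 with an estimated correlation). Of the MHC class II genes, 0 rose and 5 fell (0 and 5 adjusted over the list alone, camera adjusted p = 1.94e-04, adjusted p = 0.216 with an estimated correlation).

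The 6 lists that passed upward had small shifts, and none kept its call with an estimated correlation. Among inflammatory cytokines, 5 rose and 3 fell (9 and 3 adjusted over the list alone, median 0.19, camera adjusted p = 0.00376, adjusted p = 0.128 with an estimated correlation). Of the dendritic cell maturation genes, 4 rose and 1 fell (6 and 1 adjusted over the list alone, median 0.13, camera adjusted p = 1.94e-04, adjusted p = 0.241 with an estimated correlation). Tnfsf9 was at 0.90 and the inducible costimulator ligand Icosl at -0.80. In the NF-kappaB list, 4 rose and 1 fell (5 and 1 adjusted over the list alone, median 0.15, camera adjusted p = 0.00103, adjusted p = 0.281 with an estimated correlation), led by Tnfaip3 (0.69), and the median became 0.0855 without heat-killed replicate 3. For cAMP-responsive genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone, median 0.094, camera adjusted p = 0.00666, adjusted p = 0.241 with an estimated correlation), led by Nr4a2 (0.95). That call was lost with camera on ranks (0.0529), against a range of 0.00104 to 0.241 over its alternatives. In sterol biosynthesis, 3 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.00376, adjusted p = 0.241 with an estimated correlation). It did not pass with fry (0.0683), against a range of 0.00106 to 0.241 over its alternatives. Among erythroid and stromal markers, 2 rose and 0 fell (2 and 0 adjusted over the list alone), with a median of 0.0787 (camera adjusted p = 0.00376, adjusted p = 0.216 with an estimated correlation). They did not pass with fry (0.0683), against a range of 8.02e-04 to 0.216 over its alternatives. The matrix protein Dcn was at 0.95. The median of the list became 0.141 without live replicate 2, 0.136 without live replicate 3 and 0.136 without heat-killed replicate 3. Mast cell, basophil and eosinophil markers did not pass as a list, and 0 rose and 3 fell (1 and 3 adjusted over the list alone, median -0.0863, camera adjusted p = 0.213). They did pass, downward, without heat-killed replicate 2 (median -0.246, camera adjusted p = 0.00979), or without both live replicate 3 and heat-killed replicate 2 (median -0.157, camera adjusted p = 0.0114), against adjusted p of 0.00979 to 0.666 over the alternatives of this list. Cpa3 was at -0.35 (SE 0.25, adjusted p = 0.579). Interferon-stimulated genes did not pass either, and 4 rose and 5 fell (5 and 7 adjusted over the list alone, median 0.0118, camera adjusted p = 0.634), with Ifi205 higher (1.20) and Ifit3 (-0.84) lower with live bacteria. Ifit3 lost its call without both live replicate 3 and heat-killed replicate 2 (0.0592, range 3.05e-04 to 0.0592 over its alternatives). Of the other lists that did not pass, MHC class I genes passed, upward, without heat-killed replicate 1 (0.0278), against a range of 0.0278 to 0.554 over its alternatives. The unfolded protein and integrated stress response passed, downward, without heat-killed replicate 3 (0.014), against a range of 0.014 to 0.645 over its alternatives. Heat shock proteins passed, upward, without live replicate 1 (0.0408), heat-killed replicate 1 (0.0351) or heat-killed replicate 2 (0.0286), or with quantile normalization (0.042), or without both live replicate 3 and heat-killed replicate 2 (0.0492), against a range of 0.0286 to 0.368 over its alternatives. With fry, which tests against no change, 2 more lists passed, both lower with live bacteria: chemokines (down, 0.00384, range 0.00384 to 0.989) and prostanoid and leukotriene genes (down, 0.041, range 0.041 to 0.992), with each range taken over the alternatives of that list. Median, mean and test differed in sign for 5 lists that did not pass, namely chemokines, interferon-stimulated genes, prostanoid and leukotriene genes, glycolysis and conventional dendritic cell markers.

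**Figure D3:**
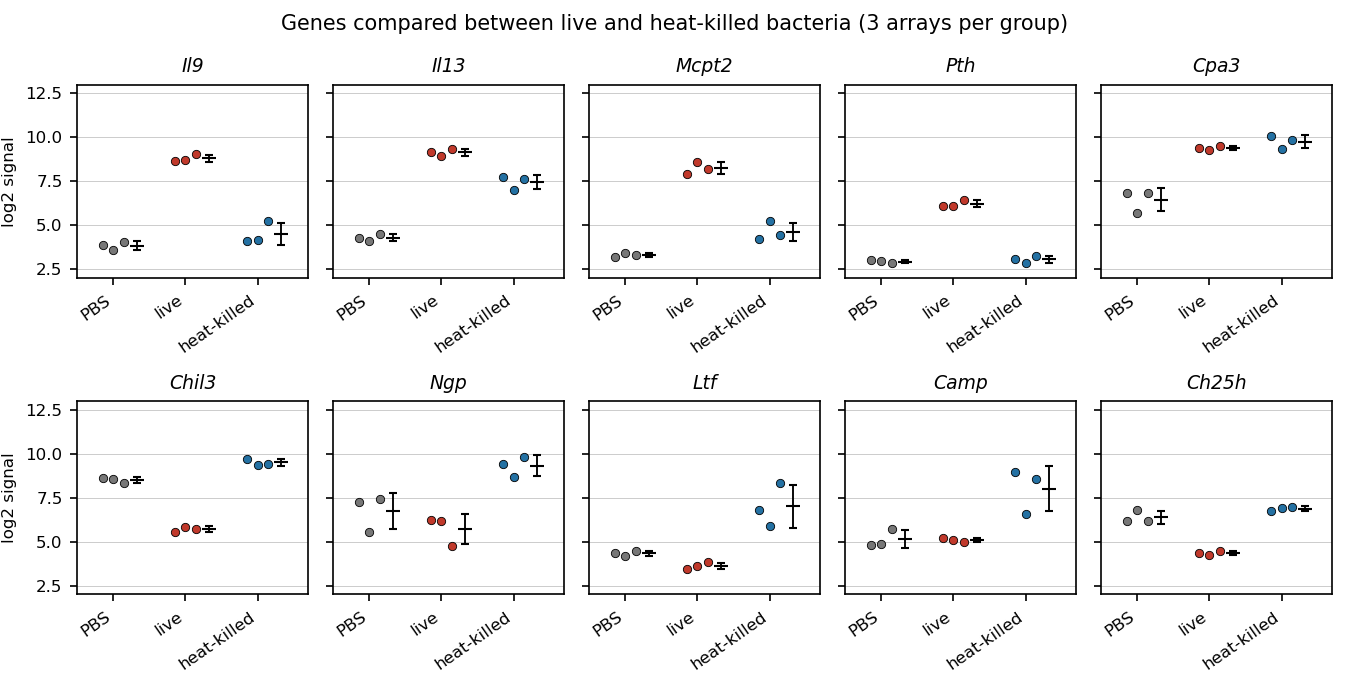
Log2 signal (vertical axis) of 10 genes on each array with PBS (grey), live (red) and heat-killed bacteria (blue); each point is 1 of 3 arrays per group, and the bar with whiskers is the group mean ± SD. Il9 measured 8.80 ± 0.20 with live and 4.49 ± 0.64 with heat-killed bacteria, Cpa3 was at 9.40 ± 0.12 and 9.75 ± 0.38 with the live and heat-killed preparations, and Ngp, Ltf and Camp were highest with heat-killed bacteria, with wide spread between replicates.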

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

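The tests of the median of lineage markers, for mast cells and for neutrophils, were chosen only after the result was seen. Probe sets outside the gene comparisons also carried signal that differed from PBS. Of 12146 probe sets with no listed gene, 820 changed with live bacteria and 734 with heat-killed bacteria, and 29 differed between the preparations. Of 1621 probe sets with several gene symbols, 162 changed with live and 173 with heat-killed bacteria, and 12 differed between the preparations. The 6 arrays of each comparison allow 10 splits, too few for a share under 0.05: in each comparison 1 of 10 splits, the real one, gave as many genes (6055 with live bacteria, 5835 with heat-killed bacteria and 1056 between them), and the highest other gave 0.

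Il9, Il13, Mcpt1 and Mcpt2, genes known from mast cells, were higher with live than with heat-killed bacteria. Il13 and Mcpt2 lay above PBS with heat-killed bacteria too, so only part of their rise over PBS separated the preparations. A larger share of mast cells or basophils in the live cultures would raise their other markers too, but the median difference of Cpa3, Fcer1a, Ms4a2, Kit, Gata2 and Hdc was -0.134 (bootstrap SE over markers 0.147), more than 2 SE below the log2 difference of 1 set as the bound. That SE measures the spread between these markers, not between arrays. Ms4a2 had no group mean above the median of all values (4.37) and decides nothing, and the other 5 lay between -0.629 and 0.187. Fcer1a lay close to that median too, with a highest group mean of 4.81. The markers were read together for mast cells and basophils, so a rise of mast cells beside a fall of basophils is not covered. A single outlying array was also argued against: over the 6 fits that each left out 1 live or heat-killed array, the lowest difference of the 4 genes was 1.48 and the highest adjusted p was 5.01e-04. A change of state in cells already present may account for the pattern, and was not tested apart from these.

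Genes grouped here as neutrophil granule genes (Ngp, Ltf, Camp, S100a8, S100a9, Ly6g and Chil3) were lower with live than with heat-killed bacteria, and all 7 stayed past the test in 6 of 6 fits that left out 1 array of either group. Ngp, Ltf, Camp, S100a8 and Chil3 were among the largest falls between the preparations in these same data, so staying past the test adds little for them. The name granule genes is loose, since not every member is a granule protein: Ly6g is a surface marker. Other markers of the same list, such as Elane and Mpo, encode granule proteins too. The grouping therefore does not separate granule genes from lineage markers. Against PBS all 7 rose with heat-killed bacteria, while with live bacteria S100a8 and Chil3 fell and the other 5 did not pass, so for most of them the difference lay in the heat-killed arrays. A smaller share of neutrophil-lineage cells in the live than in the heat-killed cultures was not decided. The other 11 markers of the list had a median difference of -0.604 (bootstrap SE over markers 0.203), against a bound of -1. Of these 11, 5 (Mpo, Cxcr2, Retnlg, Fcnb and Csf3r) had no group mean above the median of all values and may lie at background, which would hide a fall, so the median decides nothing. The other 6 lay between -1.40 and -0.436, and the share of such cells cannot be told apart from a change within cells. Arrays may also differ within a group in such cells, since the granule genes' deviations from their group means correlated at 0.357 on average, against a median of 0.0273 and a highest value of 0.645 in 1000 random sets matched on spread. The bound set before that value was seen counted any value within the range of the random sets against the explanation, and 0.357 met it. After the value was seen this bound was replaced as too strict, because some matched sets hold co-varying genes themselves and only 27 of 1000 reached 0.357, so the explanation is left open.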

How the results depend on the processing

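The fits without a pair of arrays that stood apart in granulocyte genes were chosen after seeing the data. Counts stayed within 1.5 times of those reported except as follows. With a minimum change of 2-fold, 1217 genes changed with live bacteria (475 higher, 742 lower), 923 with heat-killed bacteria (403 and 520) and 130 between them (25 and 105), with 839 shared, since fewer genes can meet both limits. Between live and heat-killed bacteria, adjusted p under 0.01 left 620 genes (157 and 463), adjustment over the 3 comparisons together gave 1620 (554 higher), and leaving out live replicate 3 and heat-killed replicate 2 left 562 (147 and 415), with fewer arrays. Camera with an estimated correlation, which widens the null, passed 11, 7 and 2 lists in place of 17, 22 and 16. Leaving out 1 array at a time gave 5307 to 6038 genes with live bacteria, 4958 to 5774 with heat-killed bacteria and 714 to 1162 between them, of which 192 to 374 were higher and 522 to 788 lower. The overlap ranged from 4309 to 4689, and lists past the test from 17 to 19, 21 to 23 and 16 to 18. With the replicate block, 6265, 6092 and 1142 genes, 5003 shared genes and 17, 22 and 16 lists passed. The share of called genes that were higher depended on scaling. With heat-killed bacteria it was 54.2%, but 47.2% after quantile normalization and 49% after median centring. With live bacteria it was 51.7%, 50% and 48.1%, and between the preparations 29.7%, 39.6% and 30.4%, in the same order. Same-number arrays of different groups correlated in their deviations from the group means at -0.0965 to 0.222, and different-number arrays at -0.289 to 0.249, and 4 of 9 same-number pairs exceeded 0.1, among them all 3 of replicate 2 (0.167 to 0.222). The 3 replicate 2 arrays, and no other array, correlated best with their own number in both other groups. Since not every same-number pair exceeded 0.1 the numbers were not read as pairs, but a shared effect on replicate 2 stays open. Over all alternatives, 2047 list results kept their direction and call, 50 lost the call, 31 gained it and 38 turned the direction of the test, with fry, whose null differs, among the alternatives. None of the lists that turned had passed the test. Their medians follow, which can keep their sign when the test turns. With live bacteria, 1 array left out gave medians of 0.0384 to 0.112 (unfolded protein and integrated stress response). Other settings turned lists at medians of 0.0116 (inflammasome and pyroptosis), 0.0787 (unfolded protein and integrated stress response) and 0.0692 (apoptosis and survival) with fry, 0.138 (MHC class II presentation) with camera on ranks, 0.0787 (unfolded protein and integrated stress response) with the 25th percentile filter, and 0.12 (unfolded protein and integrated stress response) with the 50th percentile filter. With heat-killed bacteria, 1 array left out gave medians of -0.0518 to 0.0368 (type I interferon genes), -0.153 to 0.00791 (inflammasome and pyroptosis), -0.0446 to 0.0168 (heat shock proteins) and -0.112 to 0.0542 (erythroid and stromal markers). Other settings turned lists at medians of -0.0671 (type I interferon genes) and -0.088 (inflammasome and pyroptosis) with the 25th percentile filter, -0.0347 (type I interferon genes) and -0.077 (inflammasome and pyroptosis) with array weights, -0.0434 (type I interferon genes) and -0.0451 (erythroid and stromal markers) without PBS replicate 2 and heat-killed replicate 2, -0.088 (inflammasome and pyroptosis) with the 50th percentile filter, -0.088 (inflammasome and pyroptosis) and -0.0433 (erythroid and stromal markers) with camera on ranks, and -0.0885 (plasmacytoid dendritic cell markers) with fry. Between the preparations, 1 array left out gave medians of -0.138 to -0.0488 (arginine and tryptophan metabolism), 0.0565 to 0.112 (conventional dendritic cell markers) and -0.0642 to -0.00597 (lymphocyte markers). Other settings turned lists at medians of 0.0534 (chemokines), 0.0138 (interferon-stimulated genes), 0.0361 (prostanoid and leukotriene genes) and 0.0527 (conventional dendritic cell markers) with the 50th percentile filter, 0.035 (chemokines) and 0.0869 (conventional dendritic cell markers) with camera on ranks, 0.0328 (prostanoid and leukotriene genes) and 0.0485 (conventional dendritic cell markers) without live replicate 3 and heat-killed replicate 2, and 0.0455 (lymphocyte markers) with the 25th percentile filter. Of the results for named genes, 4264 kept their direction and call, 49 lost the call, 6 gained it and 10 changed sign. Those that changed sign were small changes with heat-killed bacteria that had not passed the test, and 1 array left out gave Il10 -0.0723 to 0.18, Il23a -0.0217 to 0.0808 and Mcpt1 -0.0659 to 0.157. Other settings gave Il23a at -0.00398 with median centring, Mcpt1 at -0.00776 with array weights and Mcpt1 at -0.024 without PBS replicate 2 and heat-killed replicate 2. Signal close to background may limit the dimmest genes, such as Il10, Il23a and Ifnb1, whose means lay below the median of all values (4.37) in every group. The cause of the moves was not tested, for these genes or for the others.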

Other observations

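Families that share a symbol stem were examined across all genes, 319 families in all, and these families and their members were chosen after their values were seen. Genes with the Schlafen stem Slfn rose with both preparations: 7 of 9 measured rose with live bacteria (median log2 change 0.862, camera adjusted p = 3.62e-04, adjusted p = 0.639 with an estimated correlation) and 8 with heat-killed bacteria (median 0.937, camera adjusted p = 1.47e-05, adjusted p = 0.53 with an estimated correlation). The stem takes in the pseudogene Slfn10-ps (1.16) and the opposite-strand transcript Slfn5os (0.30), which count among the rises with live bacteria. Slfn1 rose by 1.98 with live and 2.88 with heat-killed bacteria, and Slfn4 by 1.67 with heat-killed bacteria. Both were lower with live than with heat-killed bacteria (-0.90 and -1.35). The guanylate-binding proteins, which act against bacteria inside cells, rose in 7 and 8 of 8 genes (medians 1.54 and 1.43), with Gbp3 at 2.27 and 2.13 and Gbp2b at 2.11 and 2.16. Of 9 ligands of the tumour necrosis factor family, 6 rose with each preparation, among them Tnfsf8 (3.02 and 2.89) and Tnfsf4 (1.81 and 1.51). Tnfsf11, the osteoclast differentiation factor, rose with live bacteria (0.64).

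Toll-like receptors went apart by member. Of 10 Tlr genes, 8 fell and 1 rose with live bacteria, and 7 fell and 3 rose with heat-killed bacteria. The lipopolysaccharide receptor Tlr4 fell (-1.01 and -0.51), whereas Tlr9, the receptor for bacterial DNA, rose (0.87 and 1.09). With heat-killed bacteria 8 of 10 genes with the Mcm stem rose (median 0.36), among them the replication helicase subunits Mcm6 (0.74) and Mcm4 (0.40). The Mcm rise was not particular to heat-killed bacteria: with live bacteria the median was 0.285, Mcm6 was at 0.68 and Mcm4 at 0.41. The median direction of each of these 5 families against PBS was the same after quantile normalization and after median centring. None of the 5 passed against PBS with an estimated correlation, where the lowest adjusted p was 0.425 (Tnfsf, heat-killed bacteria). Genes lower with live and higher with heat-killed bacteria, also chosen after their values were seen, were the platelet factor Pf4 (-0.67 and 0.95) and Ly6e (-0.59 and 0.34).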
